A study of Mus musculus with 9 samples.

How the data were processed

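Gene expression was measured on Illumina mouse bead arrays in 9 samples of mouse liver, with 3 samples in each of 3 groups. Per the labels' protocols, liver tissue was fixed on a glass slide, cells were collected by laser capture microdissection, RNA was extracted with Tri-reagent, and cDNA was made with Superscript II from an oligo-dT primer. The arrays carried a single dye, Cy3. The groups were taken from the sample titles. PV was the glutamine synthetase subcompartment of the perivenous zone, the sheath of hepatocytes around the central vein. NPV was zones 1+2 of the hepatic acinus, the hepatocytes farther towards the portal tract. SC was tissue scraped whole from the slide. How the PV cells were recognised under the microscope, the sex, age and strain of the mice, and the number of animals are not given in the sources used here. The labels do not tie the samples to animals, so some may share an animal, and the p-values measure only the spread between these samples, which may be technical.

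The deposited scanner table held, per the file headers, an intensity and a detection p-value for each of 45281 probes on each array, and BeadStudio 3 is named in the submitters' processing notes. These intensities had not been normalized between arrays, with medians from 71.7 to 100.2. Probes with a deposited detection p-value under 0.05 numbered from 16819 (37.1%) to 18721 (41.3%) per array. A further table deposited by the authors held processed intensity values on a linear scale, with array medians from 80.59 to 80.65 and the same maximum, 65956 on each array. How it was made is not given in the sources used here, and such close medians and equal maxima show only that the arrays had been brought to a common scale. Its ranks matched those of the scanner intensity on each array (rank correlation 1). It was used only as an alternative.

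Background was corrected by limma's neqc, with the mean and spread of the negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.05 on at least 3 of the 9 arrays were kept (19425 probes). The lowest detected log2 level was 5.05 to 5.27 per array and the highest level of any probe 16.03. Gene names were updated through the RefSeq gene table of assembly GRCm38.p6, used only for names. By accession without version 29370 probes matched, by current symbol 3678 and by a unique synonym 3273, and 8960 kept the name in the file. The files name no genome build, so no coordinates are given. Each gene was represented by its probe with the highest mean over the 9 arrays, chosen without regard to group. This left 13532 genes, 2349 of them under the name in the file and 4152 with more than 1 probe past the filter. Values of other probes of a gene are given where a probe had the opposite direction between the groups compared, and for some genes where only the size differed.

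Each comparison (PV with NPV, PV with SC, NPV with SC) was a contrast in a single limma model of the 3 group means over the 9 arrays, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The model had 6 residual degrees of freedom and a median residual SD of 0.295 on the log2 scale. All SE values and adjusted p-values of genes come from limma, and folds are ratios of geometric means of background-corrected intensity, which the offset draws towards 1 for dim genes. The 3 comparisons share arrays and are not independent of one another. Gene lists, 28 in number, were tested with limma's camera, which sets the genes of a list against the other genes tested (correlation preset to 0.01, 2-sided, adjusted over the lists). Camera was repeated with the correlation estimated from the data, and the lists were also tested with fry. Members were adjusted over all genes and over the list alone. The lists, the tests, the rule for named genes and the first set of alternatives below were fixed before the data were examined. Some lists share members: of the measured genes, 15 of 26 pericentral, 17 of 29 periportal, 8 of 16 glutamine, 4 of 8 urea cycle and 8 of 35 cytochrome P450 genes were also in another list. The smallest p of an exact permutation test of 3 against 3 unpaired arrays is 0.1.

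Glul was named in every comparison because glutamine synthetase names the captured compartment. The other named genes were up to 10 per direction (5 for the comparisons with SC) by fold change among genes past the threshold whose groups did not overlap, filled up to 5 by the smallest p where fewer passed, and up to 4 members of each list by the smallest p. RIKEN, LOC and similar names were skipped by this rule, and genes named outside it are marked as chosen after their values were seen. Results of some genes that the rule takes are not reported here. Where a gene was not detected on any array of the dimmer group, the fold is given as a bound. It sets the mean log2 level of the brighter group against the mean, over the dimmer arrays, of the higher of the lowest signal among detected probes and the gene's own signal.

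The sample titles carry the numbers 1 to 3 in each group, with number 3 written after the letters and numbers 1 and 2 before them. The labels do not say what a number marks. The correlation across genes of the deviations from the group means was 0.581 to 0.885 between arrays of the same number and at most 0.418 between arrays of different numbers. All 9 arrays were closest to the arrays of their own number. Since every correlation within a number was over 0.1, the criterion set beforehand, the numbers were taken to pair the samples. Arrays numbered 1 also correlated with those numbered 2 above 0.1 (0.324 to 0.418). The criterion alone therefore does not part numbers 1 and 2. The fit reported first had been fixed without this pairing, so its spread includes the differences between numbers. The fit with the number as a block (4 residual degrees of freedom, median residual SD 0.175) is given beside a result where it changes the call. SE values are on the log2 scale, also beside folds. Unless the block is named with them, they come from the fit without it, also for genes called with the block.

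The procedure was tested on simulated data, with 200 of 13532 genes changed between PV and NPV in each of 5 runs. Without the block it recovered 0 of 335 genes changed 1.5-fold, 14.3% of those changed 2-fold and 75.2% of those changed 4-fold, and 0 of 296 calls were false. With the block it recovered 35.8%, 97.3% and 100% of these, and 57 of 833 calls (6.84%) were false. The simulated differences between numbers were the same in every group, and the noise was that of the block fit. The gain from the block was therefore built in. Where numbers differ unlike between groups, these rates need not hold. A list of 20 genes with a planted change was called in 5 of 5 runs and an unchanged list in 0, with either correlation and in both fits. The simulated noise was independent between genes and the lists were drawn at random. These runs therefore cannot show how often camera falsely calls lists whose members vary together, such as cholesterol synthesis (estimated correlation 0.670).

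The alternatives tried were no background correction, an offset of 50, median scaling in place of quantile normalization, the authors' table, no filter, a stricter filter (detection p under 0.01 on all arrays of a group), every probe tested, only the groups compared, the number as a fixed or random block, the label style as a block, array weights, a trended and robust variance, and leaving out each array in turn. Leaving out the arrays numbered 3 and several combinations with the block were added after the data had been seen. Ranges over settings include the fit as reported, and those of lists are of camera alone, without fry. A block by slide was not run because the files name no slide. The software was R 4.3.3, limma 3.58.1 and the data.table package, version 1.17.8.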

Results

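Transcripts of mouse liver were measured in 3 kinds of sample with 3 arrays each. PV was named for the layer of hepatocytes around the central vein that makes glutamine synthetase, and NPV for zones 1+2. SC was undissected tissue from the slide. Laser capture microdissection lifts selected cells from a section under the microscope. Between 16819 and 18721 of the 45281 probes were detected per array, and 13532 genes were tested. The number of arrays limits the precision. The 3 arrays numbered 3 stood apart from the others in every group: across genes, which are not independent replicates, their levels correlated with those of numbers 1 and 2 at r = 0.944 to 0.959, against 0.981 to 0.989 between numbers 1 and 2. The arrays of each number are called a set.

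The first comparison was between PV and NPV, the sheath around the central vein and the hepatocytes of zones 1+2. Sp5, a transcription factor induced by Wnt signalling, rose 4.99-fold in PV (8.90 ± 0.11 against 6.59 ± 0.34, log2 intensity ± SD, n = 3; SE 0.20; adjusted p = 0.0203), and Rdh9, a retinol dehydrogenase, rose 3.59-fold (11.51 ± 0.11 against 9.67 ± 0.23; SE 0.17; adjusted p = 0.0203). Rhbg, an ammonium transporter, was 6.88-fold higher in PV (log2 2.78, SE 0.34), and Tnfrsf19, a receptor of the tumour necrosis factor family, 4.24-fold higher (log2 2.08, SE 0.27). On the other side Etnppl, which breaks down phosphoethanolamine, was 1.86-fold lower in PV (log2 -0.90, SE 0.21), Ak4, an adenylate kinase, 1.84-fold (SE 0.23), Sulf2, a heparan sulphate sulphatase, 1.64-fold (SE 0.19), Galc, which degrades galactosylceramide, 1.56-fold (SE 0.15), and Cyp2f2, a cytochrome P450 of periportal cells, 1.48-fold (SE 0.15). Each of these 9 genes went the same way in 3 of 3 numbered sets, which their choice from the same arrays favours. Rhbg (adjusted p = 0.0739) and Tnfrsf19 (0.0761) did not pass, and did with the replicate number as a block (adjusted p = 0.000393 and 0.000880, with ranges of 0.000393 to 0.310 and 0.000602 to 0.487 over 20 settings), and the 5 lower genes passed in neither fit. Another probe of Sulf2 differed by -0.043.

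Glul, which encodes glutamine synthetase, had a level of 13.14 ± 0.51 in PV, 10.84 ± 0.32 in NPV and 11.57 ± 0.13 in SC (log2 intensity ± SD, n = 3). It was 4.94-fold higher in PV than in NPV (log2 2.31, SE 0.27), and every PV array lay above every NPV and SC array. An exact 2-sided permutation test of PV against NPV gave p = 0.1, the smallest that 3 against 3 arrays allow. Its adjusted p was 0.0639, and 0.00220 with the block, with a range of 0.000947 to 0.298 over 20 settings. Because this gene names the compartment, its level checks the labels and is not a finding between the regions.

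**Figure D1:**
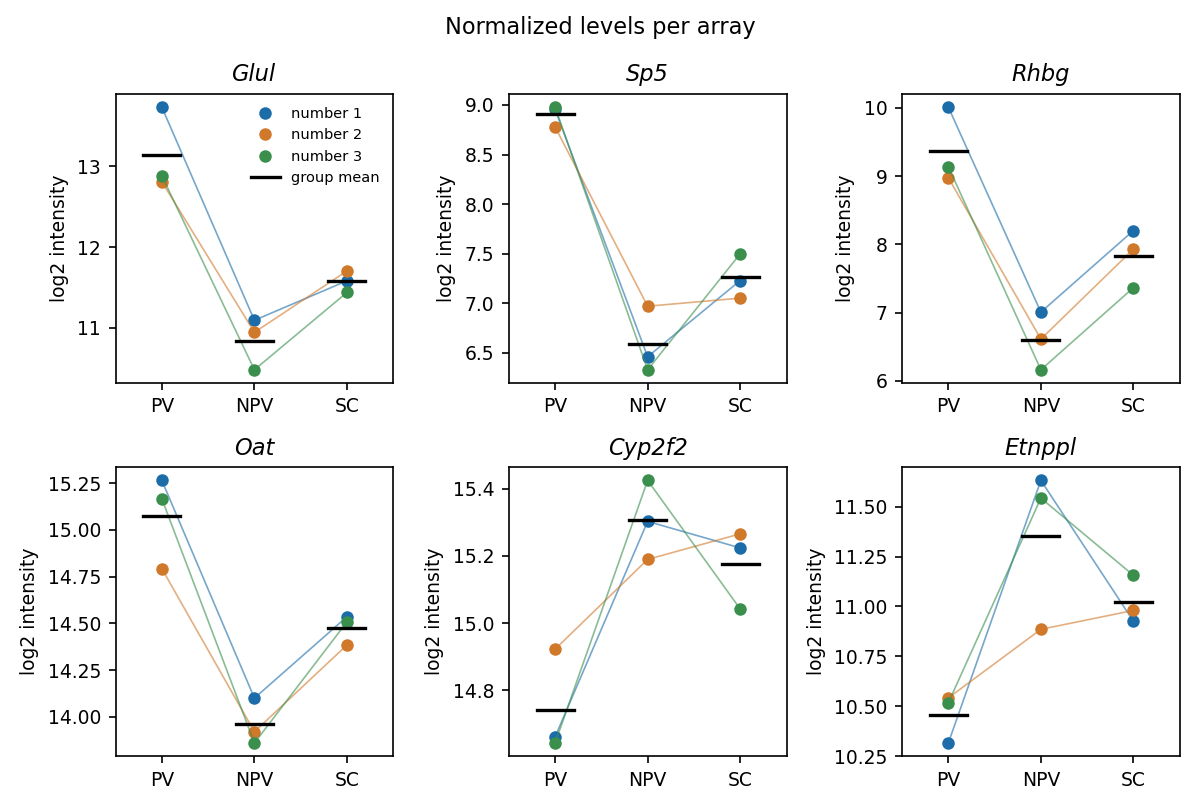
Normalized level (log2 intensity, vertical axis) of 6 genes on each of the 9 arrays, by group. Points are arrays, thin lines join arrays of the same number and black bars are group means; Glul, Sp5, Rhbg and Oat were highest in PV and lowest in NPV for each number, with SC between, while Cyp2f2 and Etnppl were lowest in PV.

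In total 3 genes rose and 0 fell by limma, with 304 at an unadjusted p under 0.05. The remaining gene that rose, 1110028F11Rik, a RIKEN transcript outside the naming rule and chosen after its values were seen, was 3.15-fold higher (SE 0.18; adjusted p = 0.0417). With the block 42 genes rose and 1 fell, with 1269 at an unadjusted p under 0.05, and the 43 called included the 3 called without it. All 43 moved the same way in each of the 3 sets, which selection by that fit favours, so this is not separate support. With the authors' table and the block the split was 74 higher and 20 lower. The gene that fell was LOC386068 (log2 -1.28, SE 0.45). It and the following, among those that rose with the block, were chosen after their values were seen. Meg3, a long noncoding RNA, was 6.94-fold higher (SE 0.67; another probe 0.22 on the log2 scale), Rcan2, a calcineurin regulator, 5.35-fold (SE 0.53; another probe 1.70), and Vldlr, a lipoprotein receptor, 4.80-fold (SE 0.92). With the block their SE values were 0.14, 0.22 and 0.23. Slc22a3, an organic cation transporter, was 3.77-fold higher (SE 0.37), Edn1, endothelin, 3.23-fold (SE 0.36) and Lpl, lipoprotein lipase, 2.85-fold (SE 0.52). Rcan2 and Edn1 were detected on 1 of 3 NPV arrays (mean log2 5.61 and 4.93), so their folds rest on NPV levels near background. The groups of 794 genes (5.87%) did not overlap, where chance gives 10% for arrays that vary independently, which those of a set did not. By limma 0 genes passed without PV 1 (231 at an unadjusted p under 0.05), PV 2 (278), NPV 1 (310) or NPV 3 (338), and 6 passed without PV 3. With the block the count was 15 without PV 1, 21 without PV 2, 15 without NPV 1 and 23 without NPV 3, and without the arrays numbered 3 it was 24 without the block and 40 with it.

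The pericentral hepatocyte markers were higher in PV as a group (26 of 28 measured, median 0.73, camera adjusted p = 6.10e-31; adjusted p = 0.00760 with an estimated correlation and 5.53e-39 to 0.121 over 24 settings). Among them 11 rose, 0 fell and 15 did not pass when adjusted over the list alone, and 19 rose with the block. Over all genes tested 0 passed, with 12 at an unadjusted p under 0.05 by limma, and 10 passed with the block. Oat, ornithine aminotransferase, was 2.17-fold higher (SE 0.17; adjusted p = 0.159, 0.00870 with the block, 0.00399 to 0.741 over 20 settings), in 3 of 3 sets. The Wnt/beta-catenin target genes were also higher (9 of 16 measured, median 1.27, camera adjusted p = 9.95e-16; adjusted p = 0.00899 with an estimated correlation and 2.81e-17 to 0.121 over 24 settings). Of these 3 rose when adjusted over the list alone, 0 fell and 6 did not pass, against 1 over all genes, and 8 rose with the block (4 over all genes). Beside Sp5 and Tnfrsf19 they included Nkd1, an inhibitor of Wnt signalling, at 2.40-fold (SE 0.37), and Lgr5, an R-spondin receptor, was 2.41-fold higher (SE 0.51; adjusted p = 1.00, 0.0306 with the block, 0.0306 to 1.00 over 20 settings). Markers of central vein endothelium, the lining of the vein that PV surrounds, moved with both groups (5 of 7 measured, median 1.16, camera adjusted p = 1.11e-07; adjusted p = 0.0230 with an estimated correlation and 1.54e-11 to 0.121 over 24 settings). Of these markers 3 rose adjusted over the list alone, 0 fell and 2 did not pass, against 0 over all genes (3 at an unadjusted p under 0.05 by limma), and 5 rose with the block. Cdh13, a cadherin, was 2.82-fold higher (SE 0.32; adjusted p = 0.709, 0.0241 with the block, 0.0158 to 1.00 over 20 settings), Lhx6, a transcription factor, 2.62-fold (SE 0.41; adjusted p = 1.00, 0.0173 with the block, 0.0173 to 1.00 over 20 settings), and Rspo3, a ligand that enhances Wnt signalling, 2.24-fold (SE 0.29), each in 3 of 3 sets, while Wnt2 was 1.95-fold higher (SE 1.05). Cdh13 and Lhx6 were detected on 1 of 3 NPV arrays (mean log2 5.10 and 4.95), so their folds rest on NPV levels near background. Stellate cell and fibroblast markers were higher too (17 of 18 measured, median 0.31, camera adjusted p = 0.0111; adjusted p = 0.251 with an estimated correlation and 2.68e-05 to 0.415 over 24 settings). By set, the median of this list was 0.61 in set 1, 0.42 in set 2 and -0.060 in set 3. Adjusted over the list alone, 0 of 17 passed, with 0 at an unadjusted p under 0.05 by limma and 4 with the block. Lum, a matrix proteoglycan, differed by 0.59 (log2, SE 0.31; another probe 0.35), Pdgfra, a growth factor receptor, by 0.35 (SE 0.24) and Reln, a secreted glycoprotein, by 0.31 (SE 0.19; another probe -4.4e-05). The stellate call was lost without PV 1 (adjusted p = 0.415), PV 2 (0.0869), NPV 2 (0.0579) or NPV 3 (0.0593) and under median scaling (0.0712).

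Periportal hepatocyte markers were lower in PV (29 of 30 measured, median -0.44, camera adjusted p = 1.01e-18; adjusted p = 0.00899 with an estimated correlation and 1.24e-24 to 0.220 over 24 settings). When adjusted over the list alone 0 rose and 0 fell, with 9 at an unadjusted p under 0.05 by limma, and 23 fell with the block. Over all genes 0 passed, and 0 with the block (23 at an unadjusted p under 0.05). Beside Etnppl and Cyp2f2, Gls2, the hepatic glutaminase, was 1.49-fold lower (SE 0.16), and Sox9, a transcription factor also found in bile ducts, 1.66-fold lower in 2 of 3 sets (SE 0.22). The urea cycle genes were lower (8 of 8 measured, median -0.29, camera adjusted p = 0.000210; adjusted p = 0.190 with an estimated correlation and 5.91e-06 to 0.309 over 24 settings). Both over all genes and adjusted over the list alone 0 passed, with 0 at an unadjusted p under 0.05 by limma, and 3 fell when adjusted over the list alone with the block. These were Cps1, carbamoyl phosphate synthetase, 1.34-fold lower (SE 0.20), Arg1, arginase, 1.27-fold (SE 0.17), and Ass1, argininosuccinate synthetase, 1.36-fold (SE 0.28), each in 3 of 3 sets. Gluconeogenesis genes were lower (11 of 13 measured, median -0.20, camera adjusted p = 0.0151; adjusted p = 0.204 with an estimated correlation and 0.00135 to 0.326 over 24 settings), although the call was lost under median scaling (adjusted p = 0.0712), with a median of 0.16 where that of all genes was 0.30. Of the 11 genes 0 passed adjusted over the list alone, with 1 at an unadjusted p under 0.05 by limma, and 1 fell with the block. It was Pck1, the cytosolic phosphoenolpyruvate carboxykinase (1.57-fold lower, SE 0.71, 3 of 3 sets). Sds, serine dehydratase, was 1.46-fold lower (SE 0.22) and Fbp1, fructose bisphosphatase, 1.30-fold lower (SE 0.22). The gluconeogenesis call was lost without NPV 1 (adjusted p = 0.326), PV 2 (0.0869) or PV 3 (0.107). Cholangiocyte markers moved with these groups (7 of 13 measured, median -0.088, camera adjusted p = 0.0212; adjusted p = 0.190 with an estimated correlation and 0.00131 to 0.778 over 24 settings), and under median scaling they were lower relative to the median of all genes (0.0021 against 0.30; adjusted p = 0.00131). Of the 7 markers 0 passed adjusted over the list alone, with 1 at an unadjusted p under 0.05 by limma, and with the block Sox9 and Krt23, a keratin (1.69-fold lower, SE 0.41), fell. The cholangiocyte call was lost without NPV 1 (0.194), NPV 3 (0.0689), PV 3 (0.247) or all arrays numbered 3 (0.259).

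Glutamine, glutamate and ammonium genes were higher in PV by the test (16 of 18 measured, median 0.012, camera adjusted p = 0.000164; adjusted p = 0.159 with an estimated correlation and 1.56e-06 to 0.309 over 24 settings), with a mean of 0.53. Of these genes 5 rose when adjusted over the list alone, 1 fell and 10 did not pass, and over all genes 0 passed (6 at an unadjusted p under 0.05 by limma) and 4 with the block. Those that rose adjusted over the list alone were Rhbg, Slc1a2, Glul, Oat and Prodh, proline dehydrogenase (log2 0.47, SE 0.16), and Gls2 fell. Slc1a2, a glutamate transporter, was 5.87-fold higher (SE 0.53; adjusted p = 0.709, 0.000390 with the block, 0.000390 to 1.00 over 20 settings). Cytochrome P450 and conjugating enzymes were higher (35 of 38 measured, median 0.18, camera adjusted p = 0.000210; adjusted p = 0.190 with an estimated correlation and 5.64e-08 to 0.274 over 24 settings). Within the group, adjusted over the list alone, 2 rose, 0 fell and 33 did not pass, over all genes 0 passed (4 at an unadjusted p under 0.05 by limma) and 2 with the block, and adjusted over the list alone with the block 11 rose and 1 fell. The gene that fell, chosen after its values were seen, was Cyp2b10, a cytochrome P450 induced by phenobarbital (log2 -0.81, SE 1.19 without the block, 3 of 3 sets). Gstm2 and Gstm3, glutathione S-transferases, were 2.49-fold (SE 0.17; adjusted p = 0.0761, 0.00870 with the block, 0.00398 to 0.489 over 20 settings) and 2.57-fold (SE 0.32; 1.00, 0.0306 with the block, 0.0237 to 1.00) higher in 3 of 3 sets, and Cyp1a2, which oxidises aromatic amines, 1.55-fold (SE 0.19). Cyp2c37 was 1.34-fold higher (SE 0.16), with another probe at 1.06 on the log2 scale. The cytochrome P450 call was lost without PV 3 (adjusted p = 0.0801) and under median scaling (0.110). Genes of cholesterol synthesis and uptake were higher by the test (17 of 19 measured, median 0.16, camera adjusted p = 0.0270; adjusted p = 0.665 with an estimated correlation and 2.36e-06 to 0.665 over 24 settings). Of the 17 genes 0 passed adjusted over the list alone, with 1 at an unadjusted p under 0.05 by limma. Nsdhl, an enzyme of sterol synthesis, differed by 0.59 (log2, SE 0.23; other probes 0.13 to 0.20) and Cyp51, another, by 0.32 (SE 0.36), which turned to -0.061 without PV 3. The cholesterol call was lost without NPV 2 (adjusted p = 0.606), PV 3 (0.0604, in the other direction) or all arrays numbered 3 (0.484, in the other direction), and under median scaling (0.107).

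**Figure D2:**
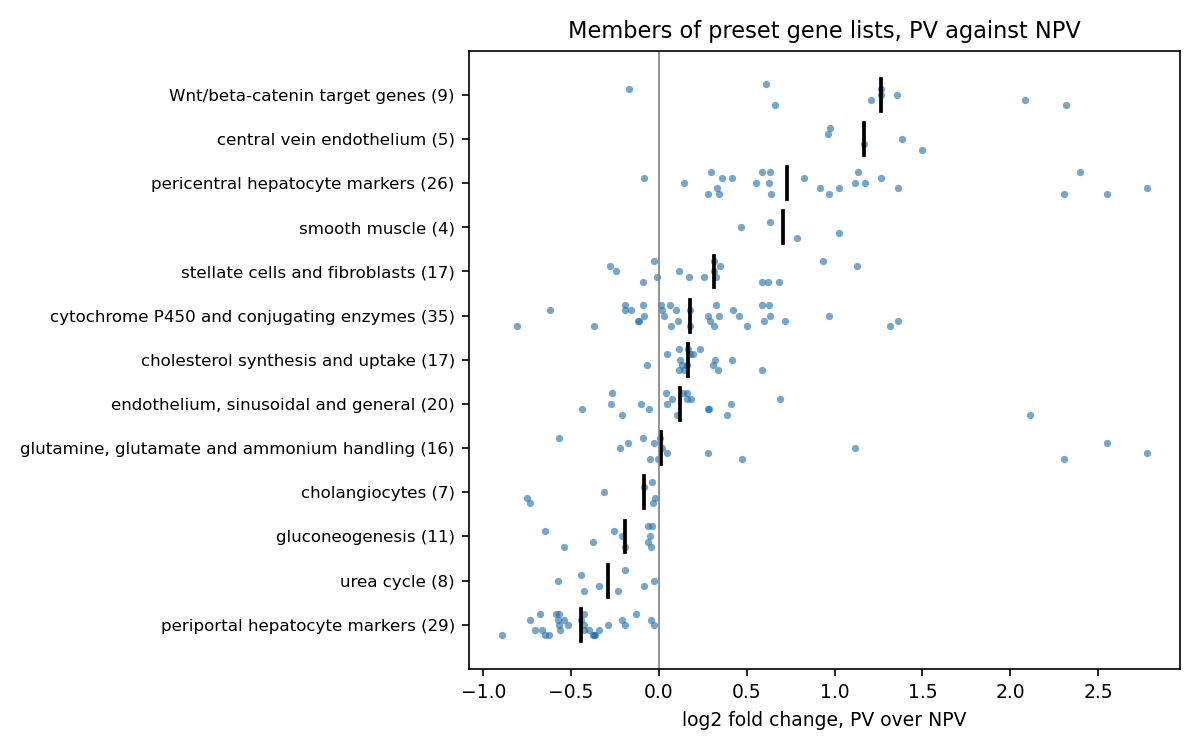
Log2 fold change of PV over NPV (horizontal axis) for the measured members of 13 gene lists, with the number measured in parentheses; each point is a gene and each black bar the list median. Pericentral markers, Wnt targets and central vein markers have medians of 0.73, 1.27 and 1.16, and periportal markers a median of -0.44.

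Between PV and NPV, camera called 11 lists, 7 higher and 4 lower. With the block it added amino acid catabolism (lower, adjusted p = 0.0313 against 0.0763 without it, adjusted p = 0.399 with an estimated correlation as well and 0.0108 to 0.601 over 24 settings) and smooth muscle markers (higher, 0.0262 against 0.146 without it, adjusted p = 0.405 with an estimated correlation as well and 0.000702 to 0.645 over 23 settings), and with both the block and an estimated correlation 0 lists passed (5 at an unadjusted p under 0.05). Among 26 amino acid genes 0 rose and 0 fell adjusted over the list alone (4 at an unadjusted p under 0.05 by limma), and 1 rose and 4 fell with the block. These were Prodh, which rose, Hal, histidine ammonia lyase (log2 -0.58, SE 0.19), Uroc1, urocanate hydratase (-0.43, SE 0.17), and, chosen after their values were seen, Amdhd1 (-0.44, SE 0.20) and Gldc (-0.40, SE 0.46). With the block Vwf, made by the lining of larger vessels (log2 2.11, SE 0.71, 3 of 3 sets), rose adjusted over the sinusoidal and general endothelium list alone and Blvrb, biliverdin reductase (log2 0.57, SE 0.17), over the haem list alone. Hal, Vwf and Blvrb did not pass over all genes in either fit. The other lists did not pass: bile acid synthesis and transport (camera adjusted p = 0.0589), fatty acid oxidation and ketogenesis (0.0633), secreted plasma proteins (0.0633), respiratory chain (0.0804), glycolysis and lipogenesis (0.148), sinusoidal and general endothelium (0.166), hypoxia-inducible genes (0.234), lymphocytes and NK cells (0.276), mesothelium (0.441), Kupffer cells and macrophages (0.628), red blood cells (0.731), haem and iron (0.848), immediate-early and stress genes (0.848), cytosolic ribosomal proteins (0.848) and neutrophils (0.961). Median, mean and test differed in sign for mesothelium (-0.015, 0.12 and higher) and neutrophils (-0.087, -0.010 and higher). Median scaling moved the median of all genes by 0.30, and relative to that shift 5 lists were higher and 5 lower, with secreted plasma proteins (lower, 1.80e-06), sinusoidal endothelium (higher, 0.00947) and stress genes (lower, 0.0309) added.

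PV was next set against SC, the undissected tissue. Glul was 2.97-fold higher in PV (log2 1.57, SE 0.27). Sp5 was 3.13-fold higher (8.90 ± 0.11 against 7.26 ± 0.23, log2 intensity ± SD, n = 3; SE 0.20), Rdh9 2.36-fold (SE 0.17), Tnfrsf19 2.68-fold (SE 0.27) and Gstm2 1.91-fold (SE 0.17), each in 3 of 3 sets. Lower in PV were Cryl1, a crystallin-like dehydrogenase, by 1.70-fold (SE 0.25), Vps37c, an endosomal sorting protein, 1.66-fold (SE 0.20), Exog, a mitochondrial nuclease, 1.46-fold (SE 0.17), and Zkscan1, a zinc finger protein, 1.43-fold (SE 0.14). Prss3, a trypsin, was detected on no PV array and was at least 1.38-fold lower. None of these passed without the block: limma called 0 genes higher and 0 lower, with 158 at an unadjusted p under 0.05 and a smallest adjusted p of 0.383. With the block 11 genes rose and 0 fell, with 840 at an unadjusted p under 0.05. They were Sp5 (adjusted p = 0.0456), Glul (0.0456), Rdh9 (0.0260), Tnfrsf19 (0.0260), Rhbg (0.0270), Slc1a2 (0.0260), Slc13a3 (0.0484) and, chosen after their values were seen, Rcan2, Meg3, Serpina7 and Endod1. Over 20 settings the adjusted p ranged from 0.0244 to 1.00 for Sp5, Rdh9 and Tnfrsf19, 0.0410 to 1.00 for Glul, 0.0270 to 1.00 for Rhbg, 0.0260 to 1.00 for Slc1a2 and 0.0484 to 1.00 for Slc13a3. The groups of 501 genes (3.70%) did not overlap, where chance gives 10% for independent arrays. With the block 0 genes passed without PV 1 (624 at an unadjusted p under 0.05 by limma), SC 1 (727), SC 2 (694) or SC 3 (1120), 6 without PV 2, 23 without PV 3 and 1 without all arrays numbered 3.

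Pericentral markers were higher in PV than SC (median 0.50, camera adjusted p = 3.17e-25; adjusted p = 0.0134 with an estimated correlation and 7.93e-30 to 0.198 over 24 settings). When adjusted over the list alone, 7 of 26 rose, 0 fell and 19 did not pass, over all genes 0 passed (9 at an unadjusted p under 0.05 by limma), and 12 rose adjusted over the list alone with the block. Slc13a3, a dicarboxylate transporter, was 3.15-fold higher (SE 0.38), Rhbg 2.91-fold (SE 0.34) and Gstm3 2.63-fold (SE 0.32), each in 3 of 3 sets. Wnt targets were higher (median 1.05, camera adjusted p = 4.27e-14; adjusted p = 0.0176 with an estimated correlation and 1.65e-15 to 0.198 over 24 settings). Adjusted over the list alone, 3 of 9 rose, 0 fell and 6 did not pass, over all genes 0 passed (3 at an unadjusted p under 0.05 by limma), and 8 rose adjusted over the list alone with the block. Beside Sp5 and Tnfrsf19, Nkd1 was 2.45-fold higher (SE 0.37) and Tcf7, a transcription factor of the Wnt pathway, 1.45-fold (SE 0.28). Central vein markers moved with them (median 0.57, camera adjusted p = 0.00882; adjusted p = 0.265 with an estimated correlation and 5.12e-05 to 0.352 over 24 settings). Among the central vein markers, adjusted over the list alone, 0 of 5 passed, with 1 at an unadjusted p under 0.05 by limma, and Cdh13 (1.74-fold higher, SE 0.32), Lhx6 (1.66-fold, SE 0.41) and Wnt2 (1.40-fold, SE 1.05) rose with the block. The SE values of these genes are from the fit without the block. The central vein call was lost without PV 1 (adjusted p = 0.289) or SC 3 (0.150), and Wnt2 turned to -0.11 and -0.33 without these arrays. Stellate cell markers were higher too (median 0.28, camera adjusted p = 0.00278; adjusted p = 0.299 with an estimated correlation and 4.13e-06 to 0.374 over 24 settings), with 0 of 17 passing when adjusted over the list alone and 0 at an unadjusted p under 0.05 by limma. Des, an intermediate filament of stellate and muscle cells, was 1.86-fold higher (SE 0.55). The stellate call was lost without PV 1 (0.216), PV 2 (0.0598) or SC 3 (0.116).

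Periportal markers were lower in PV than SC (median -0.27, camera adjusted p = 2.13e-09; adjusted p = 0.0509 with an estimated correlation and 1.26e-12 to 0.352 over 24 settings). Both over all genes and adjusted over the list alone 0 of 29 passed, with 4 at an unadjusted p under 0.05 by limma. Etnppl was 1.48-fold lower (SE 0.21), Sox9 1.43-fold (SE 0.22), Hal 1.39-fold (SE 0.19) and Cyp2f2 1.35-fold (SE 0.15), each in 3 of 3 sets. The calls of the pericentral, Wnt and periportal lists held without each array in turn. Urea cycle genes were lower (median -0.18, camera adjusted p = 0.0117; adjusted p = 0.343 with an estimated correlation and 0.000616 to 0.474 over 24 settings), with 0 of 8 passing when adjusted over the list alone and 0 at an unadjusted p under 0.05 by limma, and the call was lost without PV 1 (adjusted p = 0.110), PV 2 (0.323) or SC 3 (0.474). Arg1 was 1.17-fold lower (SE 0.17). Cholangiocyte markers were lower (median -0.29, camera adjusted p = 0.0386; adjusted p = 0.299 with an estimated correlation and 0.00460 to 0.610 over 24 settings). Adjusted over the list alone, 0 of 7 passed, with 1 at an unadjusted p under 0.05 by limma, and Krt23 (1.52-fold lower, SE 0.41) fell with the block. The cholangiocyte call was lost without PV 1 (0.110), PV 3 (0.440), SC 1 (0.136), SC 2 (0.266), SC 3 (0.0542) or all arrays numbered 3 (0.142). Red blood cell markers were lower (median -0.37, camera adjusted p = 0.0224; adjusted p = 0.400 with an estimated correlation and 6.28e-05 to 0.557 over 24 settings). When adjusted over the list alone, 0 of 7 passed, with 0 at an unadjusted p under 0.05 by limma, and the haemoglobin genes Hbb-bt (1.32-fold lower, SE 0.32) and Hbb-b1 (1.30-fold, SE 0.34) fell with the block. The red cell call was lost without PV 2 (0.0863), PV 3 (0.557), SC 1 (0.502), SC 3 (0.0718) or all arrays numbered 3 (0.0739).

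Glutamine, glutamate and ammonium genes were higher in PV than SC (median 0.085, camera adjusted p = 0.000730; adjusted p = 0.261 with an estimated correlation and 3.91e-05 to 0.352 over 24 settings). Adjusted over the list alone, 3 of 16 rose, 0 fell and 13 did not pass, and over all genes 0 passed (4 at an unadjusted p under 0.05 by limma). These were Glul, Rhbg and Oat (1.51-fold, SE 0.17), and with the block Slc1a2 (2.83-fold, SE 0.53) rose as well. The call was lost without SC 3 (adjusted p = 0.0726). Cytochrome P450 and conjugating enzymes were higher (median 0.081, camera adjusted p = 0.00288; adjusted p = 0.311 with an estimated correlation and 2.98e-06 to 0.369 over 24 settings). Among these enzymes, adjusted over the list alone, 2 of 35 rose, Gstm2 and Gstm3, 0 fell and 33 did not pass, over all genes 0 passed (2 at an unadjusted p under 0.05 by limma), and 3 rose with the block, Gstm6 (log2 0.62, SE 0.29) among them, and 1 fell, again Cyp2b10 (log2 -0.54, SE 1.19). The call was lost without PV 3 (0.369) and under median scaling (0.0871). Genes of cholesterol synthesis were higher (median 0.20, camera adjusted p = 0.00306; adjusted p = 0.487 with an estimated correlation and 1.75e-08 to 0.627 over 24 settings), with 0 of 17 passing when adjusted over the list alone and 0 at an unadjusted p under 0.05 by limma. Nsdhl was 1.43-fold higher (SE 0.23), and the call was lost without SC 2 (0.229), PV 3 (0.105, in the other direction) or all arrays numbered 3 (0.613, in the other direction). Smooth muscle (median 0.89, camera adjusted p = 0.0324; adjusted p = 0.416 with an estimated correlation and 4.12e-05 to 0.666 over 23 settings) and mesothelium markers (median 0.38, camera adjusted p = 0.00515; adjusted p = 0.306 with an estimated correlation and 0.000692 to 0.414 over 23 settings) were higher in PV, with 0 of 4 and 0 of 6 passing when adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05 by limma. Acta2, smooth muscle actin, was 2.42-fold higher (SE 1.48; other probes 0.38 and 1.17 on the log2 scale) and turned to -0.31 without PV 1. Gpm6a, a membrane glycoprotein, was 2.47-fold higher (SE 0.70). The smooth muscle call was lost without PV 1 (0.666, in the other direction), SC 2 (0.176) or SC 3 (0.303) and the mesothelium call without PV 2 (0.280) or SC 3 (0.143). Camera called 13 of the 28 lists, 9 higher and 4 lower, and 7 without SC 3. The block added gluconeogenesis (lower, adjusted p = 0.0341 against 0.118 without it, adjusted p = 0.408 with an estimated correlation as well and 0.0213 to 0.665 over 24 settings), and with both the block and an estimated correlation 0 passed (3 at an unadjusted p under 0.05). Median scaling moved the median of all genes by 0.15 and added secreted plasma proteins (lower, 0.000375). Median and mean differed in sign for haem and iron (0.012 and -0.012), stress genes (0.034 and -0.039), sinusoidal endothelium (-0.012 and 0.056) and Kupffer cells (-0.023 and 0.020), which did not pass, although with the block Vwf (log2 1.58, SE 0.71) and Cd74, the invariant chain (log2 0.53, SE 0.25), rose adjusted over the lists of sinusoidal endothelium and Kupffer cells alone.

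The last comparison was between NPV and SC. Glul was 1.67-fold lower in NPV (log2 -0.74, SE 0.27), Rhbg 2.36-fold lower (6.59 ± 0.42 against 7.83 ± 0.43, log2 intensity ± SD, n = 3; SE 0.34) and Rspo3 2.18-fold lower (SE 0.29), each in 3 of 3 sets. Lck, a T cell kinase, was at least 1.34-fold lower in NPV, Rps6kb1, the ribosomal S6 kinase, at least 1.56-fold, Mep1b, a meprin subunit, at least 1.19-fold, Lats1, a kinase of the Hippo pathway, at least 1.17-fold, and Gnat3, a taste G protein, at least 1.14-fold, since none was detected on any NPV array. Nup54, of the nuclear pore, was at least 1.32-fold higher in NPV, Ypel4 at least 1.24-fold and Slc6a4, the serotonin transporter, at least 1.12-fold, since none was detected on any SC array. Galc was 1.51-fold higher (SE 0.15; another probe 0.17 on the log2 scale) and Cyb5d2 differed by 0.45 (log2, SE 0.14; another probe -0.020). None of these passed over all genes, although Lck fell adjusted over the lymphocyte list alone: limma called 0 genes higher and 0 lower, with 211 at an unadjusted p under 0.05, and 0 with the block, with 896 at an unadjusted p under 0.05 and a smallest adjusted p of 0.293. The groups of 570 genes (4.21%) did not overlap, where chance gives 10% for independent arrays.

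As a group, pericentral markers were lower in NPV than SC (median -0.21, camera adjusted p = 1.76e-05; adjusted p = 0.181 with an estimated correlation and 1.09e-07 to 0.625 over 24 settings). Among these markers, adjusted over the list alone, 0 of 26 passed, with 4 at an unadjusted p under 0.05 by limma, and 5 fell with the block. Beside Glul and Rhbg these were Oat (1.43-fold lower, SE 0.17), Slc1a2 (2.07-fold, SE 0.53) and, chosen after its values were seen, Slc13a3 (1.67-fold, SE 0.38). The pericentral call was lost without SC 3 (adjusted p = 0.0563). Wnt targets were lower (median -0.21, camera adjusted p = 0.00806; adjusted p = 0.400 with an estimated correlation and 4.19e-05 to 0.770 over 24 settings). Adjusted over the list alone, 0 of 9 passed, with 2 at an unadjusted p under 0.05 by limma, and Sp5 (log2 -0.67, SE 0.20) and Tnfrsf19 (1.58-fold lower, SE 0.27) fell with the block. The Wnt call was lost without NPV 1 (0.120), SC 3 (0.770) or all arrays numbered 3 (0.137). Central vein markers moved with both groups (median -0.65, camera adjusted p = 0.000360; adjusted p = 0.181 with an estimated correlation and 9.89e-07 to 0.625 over 24 settings). When adjusted over the list alone Rspo3 fell and 4 did not pass, and with the block Cdh13 (1.63-fold lower, SE 0.32), Lhx6 (1.57-fold, SE 0.41) and Wnt2 (log2 -0.48, SE 1.05) fell as well. Cdh13 and Lhx6 were detected on 1 of 3 NPV arrays, so these folds rest on levels near background. The central vein call was lost without NPV 3 (0.0541), where Wnt2 turned to 0.42. Periportal markers were higher (median 0.22, camera adjusted p = 2.98e-05; adjusted p = 0.181 with an estimated correlation and 1.49e-07 to 0.625 over 24 settings), and their call held without each array in turn. When adjusted over the list alone, 0 of 29 passed, with 0 at an unadjusted p under 0.05 by limma. Gls2 was 1.23-fold higher (SE 0.16), Etnppl 1.26-fold (SE 0.21) and Sds 1.26-fold (SE 0.22). The block added glutamine, glutamate and ammonium genes (lower, adjusted p = 0.0431 against 0.0604 without it, adjusted p = 0.707 with an estimated correlation as well and 0.00635 to 0.707 over 24 settings), of which 4, Glul, Rhbg, Oat and Slc1a2, fell adjusted over the list alone against 0 without the block (3 at an unadjusted p under 0.05 by limma). It also added sinusoidal endothelium (lower, 0.0276 against 0.155 without it, adjusted p = 0.707 with an estimated correlation as well and 0.000250 to 0.960 over 24 settings) and red blood cells (lower, 0.00104 against 0.155 without it, adjusted p = 0.625 with an estimated correlation as well and 0.00104 to 0.947 over 24 settings). Of the red cell markers 2 fell when adjusted over the list alone with the block, among them Hbb-b1 (1.29-fold lower, SE 0.34), and 0 without it (0 at an unadjusted p under 0.05 by limma). Camera called 4 of the 28 lists, 1 higher and 3 lower, 8 without NPV 2 and 7 without SC 3, and fry called 0 (1 at an unadjusted p under 0.05). With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and with the block as well 0 (1). Median scaling moved the median of all genes by -0.14, and 8 lists were then called, 2 higher and 6 lower. Median and mean differed in sign for glycolysis and lipogenesis (-0.026 and 0.0015) and bile acid synthesis (0.020 and -0.037), and stress genes had a median of -0.025 and a mean of -0.0096 with a test in the other direction.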

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

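The tests without the arrays numbered 3, those without set 1 or set 2 under the block, and the block with the authors' table, with no filter, with an estimated correlation or without single arrays were chosen only after the result was seen. All other alternatives were fixed before the data were examined, and a block by slide was not run because the files name no slide. Signal over background limits the low end, since the lowest detected log2 level was 5.05 to 5.27 per array. Where 1 array was left out, the remaining pair was assumed to vary like the other groups. For the changes below the cause was not tested, except that the fit of only the groups compared used 6 arrays and fewer genes.

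Between PV and NPV limma called 3 genes. It called 6 without background correction, 5 with an offset of 50, 8 with median scaling, 6 with the authors' table, 7 with the stricter filter, 12 with array weights and 8 with a trended and robust variance. With only the groups compared it called 0 of 12747 genes (258 at an unadjusted p under 0.05). The replicate block gave 43, a random block 33 and the label style as a block 31. Leaving out 1 array gave 0 to 6, with 0 without PV 1 (231 at an unadjusted p under 0.05), PV 2 (278), NPV 1 (310) or NPV 3 (338) and 6 without PV 3. Without the arrays numbered 3 it was 24, and 40 with the block. Under the block it was 10 without set 1, 14 without set 2, 94 with the authors' table and 23 with no filter. The block without single arrays gave 15 (PV 1), 21 (PV 2), 64 (PV 3), 15 (NPV 1), 34 (NPV 2) and 23 (NPV 3).

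Camera called 11 lists between PV and NPV, 4 with an estimated correlation and 0 with the block as well (5 at an unadjusted p under 0.05). Fry called 3, and leaving out 1 array gave 11 to 13. The split of 7 higher and 4 lower became 10 and 2 without NPV 1, and 5 and 6 without NPV 2. Without PV 3, 7 of the 11 calls were kept. Glul, with a log2 difference of 2.31, passed the threshold without background correction (2.27), with an offset of 50 (2.28), median scaling (2.63), the authors' table (2.27) or array weights (2.19). It also passed, at 2.31, with the stricter filter, the replicate block, the random block, the label style or the trended and robust variance. It passed in 10 of 20 settings, and ranged over 2.01 to 2.47 with 1 array left out. Sp5 and Rdh9 each passed in 15 of 20, with adjusted p of 0.000625 to 0.174 for Sp5 and 0.000537 to 0.174 for Rdh9.

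Between PV and SC limma called 0 genes (158 at an unadjusted p under 0.05) and 0 with each array left out in turn (106 to 320 at an unadjusted p under 0.05). The replicate block gave 11, the random block 5 and the label style 4. Under the block the count was 31 with the authors' table, 1 without the arrays numbered 3, 0 without set 1 (656 at an unadjusted p under 0.05) or set 2 (669), and 0 with no filter (1512). Without single arrays the block gave 0 to 23, with 6 without PV 2 and 23 without PV 3. It gave 0 without PV 1 (624 at an unadjusted p under 0.05), SC 1 (727), SC 2 (694) or SC 3 (1120). Lists numbered 13, 2 with an estimated correlation, 2 with fry, 0 with the block and an estimated correlation (3 at an unadjusted p under 0.05), and 7 to 11 without 1 array, the lowest without SC 3.

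Between NPV and SC limma called 0 genes (211 at an unadjusted p under 0.05) and 1 with the block and the authors' table. Lists numbered 4, 8 with median scaling, 7 with the replicate block and 7 with the label style. They numbered 0 with an estimated correlation (3 at an unadjusted p under 0.05), 0 with fry (1), 0 with the block and an estimated correlation (1), and 4 to 8 without 1 array, with 8 without NPV 2 and 7 without SC 3. Every other count stayed within 1.5 times that reported, and the block changed no other call of a list, or of a gene in a comparison in which its value is given. Further genes that passed with the block alone are given only in the counts.

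Over the pairs of a named gene and a setting, direction and side of the threshold stayed in 2214, the call was gained in 61 and lost in 10, and the direction turned in 18. None of the genes that turned had passed over all genes, with or without the block, in the comparison in which it turned. With median scaling PV over NPV was 0.14 for Mdh1 (its other probes, without that scaling, 0.093 and -0.023) and 0.0021 for Cldn7, and PV over SC was 0.036 for Otc, each below the shift of all genes (0.30 and 0.15). With 1 array left out, PV over NPV was -0.026 to 0.65 for Idi1 and -0.061 to 0.56 for Cyp51, which turned without PV 3, and -0.23 to 0.11 for Cldn7 (PV 2, NPV 1). PV over SC was -0.56 to 0.0013 for Asl (SC 3), -0.072 to 0.95 for Lss (PV 3), -0.22 to 1.77 for Thbd and -0.33 to 1.40 for Wnt2 (PV 1, SC 3). It was -0.13 to 1.27 for Tpm2, -0.13 to 1.45 for Myl9 and -0.31 to 2.39 for Acta2 (PV 1). NPV over SC was -0.82 to 0.15 for Lgr5 (SC 3) and -1.29 to 0.42 for Wnt2 (NPV 3).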

Other observations

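The tests of the hepatocyte share, of the vein wall and of Cyp2e1 were chosen only after the result was seen, as were the genes named by set here and the reading of the probe test. Each numbered set holds 1 PV, 1 NPV and 1 SC array, and since the labels do not say what a number marks, no gene was tested between sets. Mt1, a metal-binding protein induced by zinc and glucocorticoids, had a mean log2 level of 12.79 in set 1, 15.42 in set 2 and 12.41 in set 3, and Mt2 had 5.57, 8.79 and 4.96. Saa1, an acute phase protein, had means of 12.29, 13.48 and 10.79, while Hp, another, had 15.46, 15.50 and 15.25 on the PV arrays of these sets. Means of Lcn2, lipocalin, were 7.41, 9.09 and 7.51. The neutrophil genes S100a8 and S100a9 had means of 7.16, 9.13 and 5.02, and of 7.49, 9.35 and 5.25. Acta2, smooth muscle actin, averaged 11.76 in set 1, with arrays from 10.29 to 13.39, against 8.28 and 8.30 in sets 2 and 3. Among clock genes Arntl averaged 5.62, 4.84 and 8.66, Dbp 13.31, 13.48 and 11.56 and Per2 10.80, 11.14 and 9.15.

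The arrays numbered 3 stood apart from numbers 1 and 2 in every group, and a hybridisation batch cannot be told apart from the number, since these arrays also share a label style. Another phase of the daily clock is a candidate explanation: with the genes already seen (Arntl, Dbp, Per2) left out, clock genes that run with Arntl minus those that run against it were higher in set 3 by 1.64 in PV, 1.62 in NPV and 1.76 in SC, against -0.41, -0.15 and 0.15 between sets 2 and 1. The contrast held 2 and 7 genes, and although Usp2 (-4.01 in NPV), Per1 (-3.42) and Ciart (-3.46) went its way, not all members did, and Nr1d1 (1.22 in NPV) went against it. Sequence variants of another mouse strain under the probes stay open: over 4152 genes the set difference correlated between probes of a gene at 0.594 for set 3 and 0.485 for set 2 against set 1, a gap of 0.108 (bootstrap SD 0.0292), which by the criterion written beforehand would have argued against them. That criterion was judged wrong after the result was seen, because a wider set difference raises the correlation by itself (SD 0.718 against 0.285). The variance not shared between probes was 4.45 times higher for set 3 (0.207 against 0.0464). A wider set difference can raise this variance too, so neither measure decides.

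Central vein endothelium markers were higher in PV than NPV in each set, with medians of 1.64, 1.11 and 0.95; of the 5 measured, 0 are in another list and 5 were detected on every PV, 2 on every NPV and 4 on every SC array. A lower share of hepatocytes in PV that raised every other cell type alike was set against the sinusoidal endothelium, Kupffer cell and lymphocyte lists. Their medians lay below the central vein median by at least 0.416 in every set, which argues against such an even rise, for these lists. Outside them, stellate medians were 0.61, 0.42 and -0.060 over the sets and mesothelium medians 0.48, 0.71 and -1.33. Cholangiocyte medians were -0.35, 0.00069 and -0.46. A lower share with an uneven rise was not tested. Vein wall captured with the hepatocytes is a possible explanation. Vwf, made by vein endothelium, was higher in PV by 1.00 to 2.84 over the sets. This 1 gene goes with vein lining in the capture, so PV may not hold hepatocytes alone. The smooth muscle median was 1.52, 0.68 and -0.025, so the explanation stays open for the rest of the wall. Of the smooth muscle list's 4 genes 0 are in another list. The list had 2, 2 and 2 detected on every PV, NPV and SC array. Its members with the brightest probes, a signal that does not rank transcripts by abundance, were Acta2, at 13.39, 9.26 and 7.98 (log2) in PV against 11.59, 7.42 and 8.55 in NPV (PV over NPV 1.02, and 0.22 and 1.08 by its other probes), and Tpm2, at 10.14, 8.21 and 7.33 against 8.67, 7.38 and 7.28. Laser capture would remove the vein wall only as far as the outline drawn excluded it, and a difference between the regions themselves, which the design names, was not tested apart from this.

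Cyp2e1, a cytochrome P450 of pericentral hepatocytes, differed by -0.088 (log2, SE 0.12, adjusted p = 1.00 by limma) between PV and NPV. Signal at the top of the scanner's range may hide a difference: its probe read from 82.4% to 100% of the highest signal on each array, which need not be the scanner's limit. In sets 2 and 3 it read 97.8% to 100%, under array maxima of 70015 to 70934.9. On PV 3 it ranked 30 at 97.8%, so signals crowded near the top there. In set 1 it read 50326.7 in PV and 50673.1 in NPV, under array maxima of 58739.5 and 57672.9. Its log2 levels there were 15.955 and 15.946. The question stays open, because that is 1 pair of arrays and 0 other probes of the gene were there to compare.

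The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. Between PV and NPV 1 split, the real one, gave 3 genes, and the highest other 0. The real split gave 11 lists and the highest other 11, so 2 splits gave as many, the other putting PV 1, PV 2 and NPV 2 together. Of the 4 splits that part every numbered pair, the highest other gave 9 lists, and with the block the real split gave 43 genes and 13 lists against 0 and 11 for the highest other. Between PV and SC all 10 splits gave 0 genes, and 1 split, the real one, gave 13 lists against 9 for the highest other. With the block the real split gave 11 genes and 14 lists against 0 and 9. Between NPV and SC all 10 splits gave 0 genes, and 4 splits gave 4 lists or more, with 6 for the highest other. With the block the real split gave 7 lists and the highest other 8. Unadjusted counts beside these gene counts of 0 were 158 between PV and SC and 211 between NPV and SC, by limma at p under 0.05 for the real split.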
